A study of Mus musculus with 48 samples.

How the data were processed

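Messenger RNA of the cerebral cortex of 48 mice was measured by RNA sequencing. Per the labels, tissue was dissected at 6 months, RNA was extracted with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq stranded protocol, and all mice are listed under a C57BL/6 background. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10, HTSeq 0.12.3 and the mouse genome GRCm38 (mm10), without the order of the steps, the annotation release, the strand setting or the filters. The deposited read counts are raw counts per Ensembl gene, as whole numbers, for 48795 genes with 1 column per mouse. The deposited FPKM table holds the same genes, scaled by gene length and library total: over 12251 abundant genes, the ratio of the authors' FPKM to the authors' counts was checked to be 1 factor per gene times 1 factor per library, to within a coefficient of variation of 3.09e-15. All columns were matched to a mouse, and no 2 libraries of the same group were copies of each other: over the 169 pairs of libraries within groups, chi-square over degrees of freedom lay between 4.71 and 37.2. The labels do not say what the column names mean, but 13 of their 27 stems (the name without its last number) span groups, and mice sharing a stem deviated together: over 23 such pairs of mice from different groups the mean r of deviations from the group and sex means was 0.154 (0.02 to 0.31), beside -0.004 for other pairs (p = 1e-04 over 10000 permutations of the stems within group and sex). A shared litter, cage or day would give this, and the fits, splits and permutation tests treat all mice as independent, apart from 1 alternative with a random block for the stem that was added after this was seen.

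Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on genotype, which left 20010 genes and removed 28785, with 99.963% of the counts kept. A generalized linear model with TMM normalization factors, the 6 genotypes and sex was fitted to all 48 mice, which share 1 estimate of the spread, and each comparison was tested with edgeR's quasi-likelihood F-test. A gene is called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were the Q140 effect within each Msh3 genotype, the effect of each altered Msh3 genotype with and without Q140, the differences between these Q140 effects, and the Q140 effect in males minus that in females, for which a Q140-by-sex term was added. Positions are from GENCODE M21, to which 48435 gene identifiers were matched, holding 99.93% of the counts. On GRCm38, 216 tested genes lie within 10 Mb of Htt and 121 within 10 Mb of Msh3. CPM values use TMM-scaled library sizes.

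For each comparison the genes to name were fixed by a rule: Htt and Msh3; the 8 higher and 8 lower called genes with the largest change, a mean CPM of at least 1 and a symbol that is not a gene model; the 2 members with the smallest p from each list that held a called gene or passed the list test; and, where fewer than 5 genes passed, the 5 with the smallest p. Some results the rule would name are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. In all, 27 gene lists for cell types and pathways were fixed. They were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, again with an estimated correlation, with fry, and with an exact permutation test of 1 mean per mouse, adjusted in the same way. Of the calls made with the preset correlation in the 10 planned comparisons, 58 in all, 0 held with the estimated one. Fry passed 4 lists and the exact permutation test 4 of 189 pairs of list and comparison, each time mismatch repair with Msh3 among its members, and without Msh3 the permutation test of that list gave p from 0.257 to 0.859 in these 4 comparisons. With camera and a simulated 1.15-fold shift of a list in Q140 against WT, that list passed with both correlations and no other did. The simulated genes varied independently of each other, so this trial does not show how either correlation setting performs on the correlated genes of these libraries.

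The Q140 signature score of a mouse is the mean over the signature genes of log2 CPM, with a prior count of 1, minus the mean over all mice, with the sign of the change in Q140 against WT. The genes are those called in Q140 against WT or, with fewer than 30, the 100 with the smallest p, in each case outside 10 Mb of Htt and Msh3. Scores were compared with two-sided exact permutation tests over all ways to divide the mice, in groups that did not choose the genes. The tests, lists, rule and alternatives, apart from those said to be added, were set before the data were examined.

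The alternatives were RLE size factors, no low-count filter and a stricter one (CPM of at least 1 in at least 7 mice), DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, limma on log2 of the deposited FPKM values plus 0.1 or plus 1, the plate column of the well as a factor, no sex term, a replicate block, only the compared groups, each mouse left out in turn for 3 of the counts, and the genes near Htt and Msh3 left out. Sets of libraries that stood apart were left out as alternatives chosen after seeing the data. The test was tried on simulated data, negative binomial counts with the means, library sizes and dispersions of these libraries, in which 200 genes were given known folds, and the share recovered is given beside the comparisons. These genes were drawn from those at a mean CPM of at least 1 and changed together, beside a 1.15-fold shift of 1 list. With fewer true changes the Benjamini-Hochberg threshold is stricter, so a comparison with few changed genes would recover smaller shares. To ask how often chance gives as many calls, 100 splits of the mice, the real one included, were fitted for each count. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No alignment was made here, so values per exon or per allele are not given.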

Results

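RNA was sequenced from the cerebral cortex of 48 mice aged 6 months, each library from a separate animal per the labels. The mice fell into 6 genotype groups: 7 wild type (WT), 8 Q140, 9 Msh3+/-, 8 Q140 x Msh3+/-, 8 Msh3-/- and 8 Q140 x Msh3-/- mice. Q140 is a knock-in allele of Htt, the huntingtin gene, with an expanded CAG repeat, carried here in heterozygous form, and Msh3 encodes a DNA mismatch repair protein that binds small loops of extra bases. WT held 3 females and 4 males, Msh3+/- 5 females and 4 males, and each other group 4 of each sex. The deposited counts summed to between 35.9 M and 64.5 M per library, with a mean of 46.5 M. Group means were 49 ± 7.44 M in WT, 46.1 ± 4.62 in Q140, 46.6 ± 4.98 in Msh3+/-, 45.5 ± 5.55 in Q140 x Msh3+/-, 46.9 ± 4.75 in Msh3-/- and 45.3 ± 6.8 in Q140 x Msh3-/- (SD over the mice of each group). At this depth a kept gene had a median of 463 counts per library. Males and females separated on the first principal component, which held 11.7% of the variance. Below, levels are library-scaled counts (CPM) with the SD over the mice of a group, changes are log2 fold changes with their standard error, and adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction over 20010 genes unless another test is named.

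The targeted genes were examined first, to set the labels against the RNA. Msh3 (ENSMUSG00000014850, GRCm38 chromosome 13, 92211872 to 92355003, minus strand) had higher, not lower, counts in every group labelled Msh3+/- or Msh3-/-, with or without Q140. Its mean level was 24.2 ± 1.06 CPM in WT (n = 7) and 23.7 ± 1.36 in Q140 (n = 8). It was 67.4 ± 5.11 CPM in Msh3+/- (n = 9) and 66.6 ± 4.17 in Q140 x Msh3+/- (n = 8), then 109 ± 7.91 in Msh3-/- (n = 8) and 113 ± 6.74 in Q140 x Msh3-/- (n = 8). Ranges of the 3 allele classes did not overlap: the highest mouse with 0 altered alleles had 25.9 CPM, mice with 1 had 61.2 to 77.4, and mice with 2 had 99.1 to 125. The RNA therefore goes against a reading of these labels as loss of Msh3 RNA, and "Msh3+/-" and "Msh3-/-" are used below as the labels' names for 1 and 2 altered alleles. Counts per gene do not show which exons were read, or whether a protein is made. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534, plus strand) had 237 ± 8.13 CPM in WT and 238 ± 7.16 in Q140, and group means from 237 to 242 CPM over all 6 groups. The tables count both Htt alleles together, so they do not show the expanded allele.

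**Figure D1:**
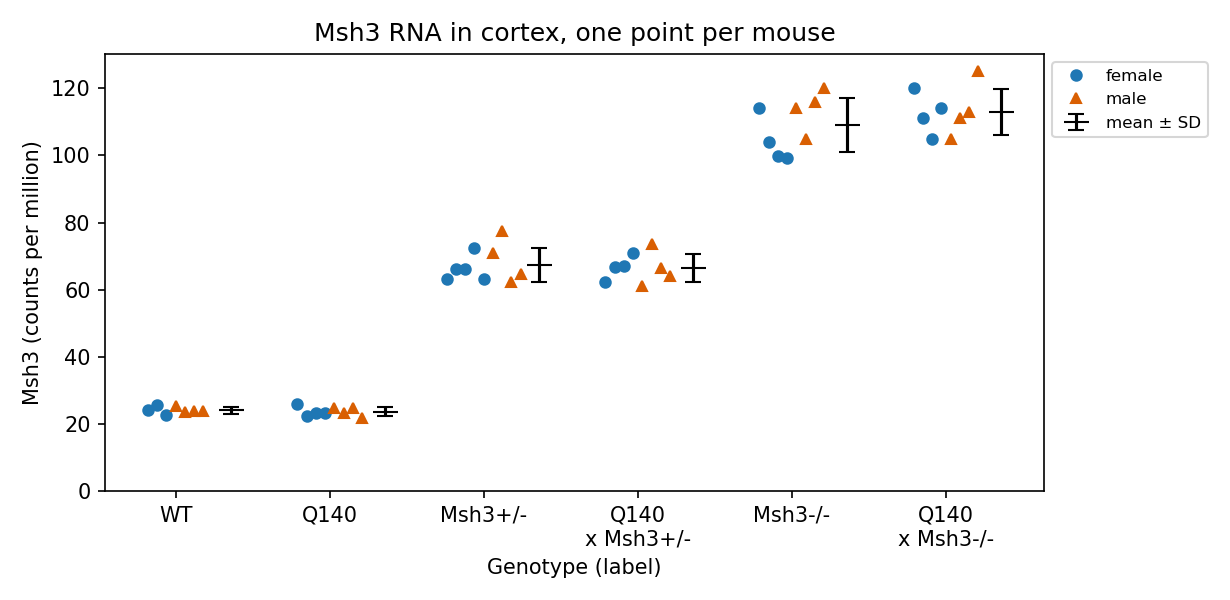
Msh3 level (CPM, linear axis from 0) in each of the 48 mice by genotype group, with the group mean and SD. Group means lie near 24 CPM with 0 altered alleles, near 67 with 1 and from 109 to 113 with 2.

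Mice labelled Msh3-/- were compared with WT to ask what the altered Msh3 alleles change in cortex without the Htt expansion. Besides Msh3, which was higher by 2.17 ± 0.05 (4.51-fold, adjusted p = 3.2e-36), the genes that changed lay close to it on chromosome 13. Rasgrf2, a guanine nucleotide exchange factor for Ras and a marker of upper-layer neurons, fell from 323 ± 24.3 to 165 ± 20.3 CPM (log2 fold change -0.96 ± 0.06, adjusted p = 4.49e-16), with the highest Msh3-/- mouse at 193 and the lowest WT mouse at 283. Cmya5, which encodes a muscle protein, fell from 16.7 ± 2.29 to 7.81 ± 0.351 CPM (-1.09 ± 0.08, adjusted p = 3.35e-15). F2r, the thrombin receptor, rose from 3.69 ± 0.697 to 6.34 ± 0.362 CPM (0.77 ± 0.09, adjusted p = 3.22e-07), and the neighbouring protease-activated receptor gene F2rl2 fell by 1.18 on the log2 scale (SE 0.17, adjusted p = 4.85e-05). The antisense transcript AW495222 fell by 1.08 (SE 0.14, adjusted p = 1.87e-06) and Fam169a by 0.26 (SE 0.04, adjusted p = 0.0011). Since the strand setting of the counting is not stated, counts of AW495222 can hold reads of Dmgdh, which it overlaps on the other strand.

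In all, edgeR called 7 genes between Msh3-/- (n = 8) and WT (n = 7), 2 higher and 5 lower, and all 7 started within 10 Mb of Msh3. DESeq2 and limma with voom weights each called 14, of which 6 lay outside that region, and the unadjusted p was under 0.05 for 1146 genes. Of the lists fixed beforehand, mismatch repair and repeat instability held 1 called gene, Msh3 itself, both over all genes and adjusted over the list alone. Camera gave it an adjusted p of 0.0166 (adjusted p = 0.245 with an estimated correlation). The per-mouse mean of its 24 members other than Msh3 differed by 0.004 (exact permutation p = 0.859, two-sided). All 18 tested oligodendrocyte and myelin genes lay below WT, with a median of -0.139 (camera adjusted p = 0.000344, and adjusted p = 0.797 with an estimated correlation), and none of them was called over all genes or adjusted over the list alone. Cholesterol biosynthesis genes lay below WT in 21 of 24 cases, among them Mvd, a decarboxylase of the mevalonate pathway, at -0.20 ± 0.08 (adjusted p = 0.848), with 1 member called adjusted over the list alone (camera adjusted p = 5.51e-05, and adjusted p = 0.692 with an estimated correlation). Per-mouse means of this list in WT were 0.149 to 0.226 in males and -0.183 to 0.049 in females. All 9 choroid plexus markers lay above WT (camera adjusted p = 0.0135, and adjusted p = 0.797 with an estimated correlation), and Ttr, the transthyretin gene that this epithelium expresses strongly, stood at 1090 CPM in Msh3-/- female 4 and 106 in female 3, against 353 in WT male 3 and at most 9.17 in any other mouse.

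Mice labelled Msh3+/- (n = 9) were compared with WT (n = 7) for the effect of a single altered allele. Msh3 was higher by 1.48 ± 0.05 (2.79-fold, adjusted p = 3.37e-29), and the changes of its neighbours had the direction seen with 2 altered alleles. F2r rose to 5.43 ± 0.833 CPM (0.54 ± 0.09, adjusted p = 0.00269), Cmya5 fell to 12.4 ± 1.87 CPM (-0.42 ± 0.07, adjusted p = 0.00323) and Rasgrf2 fell to 259 ± 20.7 CPM (-0.30 ± 0.06, adjusted p = 0.0352). Away from chromosome 13, Kcnv1, a modifying subunit of voltage-gated potassium channels on chromosome 15, rose by 0.19 ± 0.03 (1.14-fold, adjusted p = 0.00452). These were the 5 genes that edgeR called, 3 higher and 2 lower, with an unadjusted p under 0.05 for 1901 genes (9.5%). DESeq2 called 12, 8 of them outside the region of Msh3, and edgeR called 1, Msh3, once the plate column of the well was a factor. Only plate columns 3 and 6 held mice of both groups, so genotype and plate column are hard to tell apart here. Without the 3 libraries apart on the second principal component, 3 of 6 called genes lay outside that region instead of 1. Rasgrf2 lost its call in 5 of the 15 settings tried for it, F2r and Cmya5 in 2 of 15 each, and Kcnv1 in 1 of 16. Immediate early genes lay below WT in 22 of 24 cases (median -0.357, camera adjusted p = 1.63e-05, and adjusted p = 0.85 with an estimated correlation) and cholesterol biosynthesis genes also in 22 of 24 (camera adjusted p = 8.17e-05, and adjusted p = 0.85 with an estimated correlation). No gene of either list was called, over all genes or adjusted over the list alone. Per-mouse means of the immediate early list in WT were 0.636 to 0.855 in males and -0.63 to 0.023 in females. For the cholesterol list they were 0.149 to 0.226 and -0.183 to 0.049. Exact permutation tests of the per-mouse means gave differences of -0.405 (p = 0.161) and -0.104 (p = 0.165, both adjusted p = 0.76). Fosl2, a subunit of the AP-1 transcription factor, stood at -0.53 ± 0.21 (adjusted p = 0.424).

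Within Q140 carriers, Q140 x Msh3-/- mice were compared with Q140 mice, which asks what the altered Msh3 alleles change when the Htt expansion is present. The same neighbours of Msh3 changed. Msh3 was higher by 2.25 ± 0.05 (4.76-fold, adjusted p = 8.21e-38), Rasgrf2 fell from 326 ± 27.9 to 176 ± 14.1 CPM (-0.89 ± 0.06, adjusted p = 3.71e-15), Cmya5 from 17.3 ± 1.49 to 8.56 ± 0.647 CPM (-1.02 ± 0.07, adjusted p = 1.27e-14), and F2r rose by 0.76 ± 0.09 (adjusted p = 1.59e-07). AW495222 fell by 1.01 (SE 0.13, adjusted p = 3.79e-06), F2rl2 by 0.88 (SE 0.17, adjusted p = 0.0101) and Fam169a by 0.25 (SE 0.04, adjusted p = 0.00112). Bhmt2, a methyltransferase gene of the same region that was named after its values were seen, fell by 1.16 (SE 0.22, adjusted p = 0.00855). Sbno1, on chromosome 5 at 124368702, rose by 0.13 ± 0.03 (adjusted p = 0.037), and it lost that call in 10 of the 16 alternative settings tried for it, as did F2rl2 in 3 of 15.

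The count for this comparison was 9 genes, 3 higher and 6 lower (n = 8 against 8), with an unadjusted p under 0.05 for 1814 genes (9.07%). DESeq2 called 12 and limma with voom weights 10. Only plate columns 1 and 3 held mice of both groups, so effects of genotype and of plate column are hard to tell apart. Both comparisons of Msh3-/- animals use separate mice, and they shared 2 higher and 5 lower genes where 3e-04 and 0.0015 would be shared if the calls were independent. All shared genes lie around Msh3, the locus altered in both comparisons, so the calls were linked by the design. Among microglial markers 15 of 18 lay below Q140, including the complement gene C1qa at -0.20 ± 0.06 and the signalling adaptor Tyrobp at -0.26 ± 0.08 (both adjusted p = 0.337, and 3 members called adjusted over the list alone). Genes of the neurotrophin and activity-dependent list lay above Q140 in 14 of 15 cases, with Homer1, a scaffold protein of the postsynapse, at 0.33 ± 0.15 (adjusted p = 0.511, and none called adjusted over the list alone). Camera gave these lists adjusted p-values of 0.0157 and 0.0217, and each had adjusted p = 1 with an estimated correlation.

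A single altered allele on the Q140 background, Q140 x Msh3+/- against Q140 (n = 8 each), gave 4 called genes, 2 higher and 2 lower. Msh3 was higher by 1.49 ± 0.05 (2.8-fold, adjusted p = 9.03e-30) and F2r rose by 0.46 ± 0.09 (adjusted p = 0.0201, a call lost in 3 of 15 alternative settings). Cmya5 fell by 0.45 (SE 0.07) and Rasgrf2 by 0.38 (SE 0.06, both adjusted p = 0.000686). Next in order was Rpl3, a ribosomal protein gene, at -0.22 ± 0.04 (adjusted p = 0.0598). Both comparisons of Msh3+/- animals shared 2 higher and 2 lower genes, against 3e-04 and 2e-04 if independent. These are Msh3 and genes around it, the locus altered in both, so the calls were linked by the design. Deep-layer neuron markers lay below Q140 in 18 of 19 cases and myelin genes in 16 of 18, with none called over all genes or adjusted over the list alone (camera adjusted p = 0.0432 for each, and adjusted p = 0.97 with an estimated correlation). DESeq2 called 5 genes and limma with voom weights 4.

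**Figure D2:**
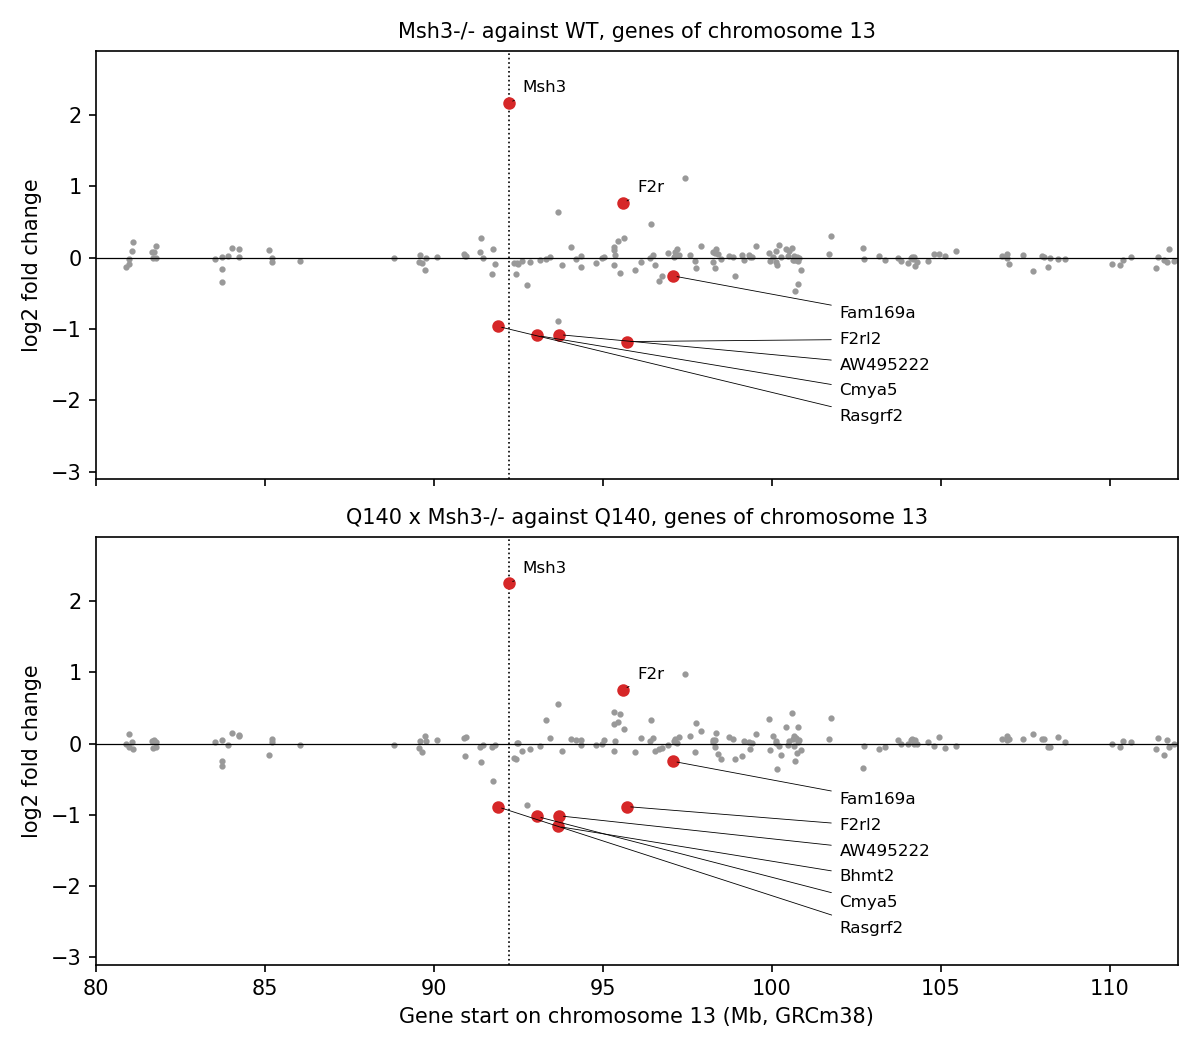
Log2 fold change of each tested gene by its start on chromosome 13 (GRCm38, Mb) around Msh3, for Msh3-/- against WT and for Q140 x Msh3-/- against Q140, with called genes in red and named and the start of Msh3 as a dotted line. Msh3 and F2r are higher in both comparisons, by 2.17 and 0.77 in the first and 2.25 and 0.76 in the other, and the remaining named genes are lower.

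Q140 mice (n = 8) were compared with WT (n = 7) for the effect of the expanded Htt allele with unaltered Msh3. Only genes close to Htt on chromosome 5 were called by edgeR. Abhd1 (ENSMUSG00000006638, 30950066 to 30955091), which encodes an alpha/beta hydrolase domain protein, rose from 2.76 ± 0.39 to 6.28 ± 0.647 CPM (1.19 ± 0.15, 2.28-fold, adjusted p = 7.31e-06), with all 8 Q140 mice at 5.32 CPM or more and all 7 WT mice at 3.32 or less. Gm2420, a transcribed pseudogene at 32720330, rose by 3.33 ± 0.49 (adjusted p = 0.000189) at a mean of 0.213 CPM. Htt itself stood at 0.00 ± 0.03 (adjusted p = 0.994), and Atraid, also on chromosome 5, stood at -0.27 ± 0.06 (adjusted p = 0.246). None of the 21 tested markers of striatal projection neurons was called.

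Lists of activity-dependent genes lay below WT in these mice as groups, with no member called over all genes. All 15 genes of the neurotrophin and activity-dependent list lay below WT, with a median of -0.251, including the transcription factor gene Crem at -0.26 ± 0.08 and Crh, corticotropin-releasing hormone, at -0.38 ± 0.13 (both adjusted p = 0.822, and 2 members called adjusted over the list alone). Immediate early genes lay below WT in 20 of 24 cases (median -0.317), among them Fosl2 at -0.62 ± 0.21 (adjusted p = 0.822) and Klf4, a zinc finger transcription factor, at -0.43 ± 0.16 (adjusted p = 0.88). Camera gave these lists adjusted p-values of 1.39e-09 and 3.78e-05, which became adjusted p = 0.224 and adjusted p = 0.632 with an estimated correlation. An exact permutation test of the per-mouse mean of the first list gave a difference of -0.23 (p = 0.0183, adjusted p = 0.494 over the 27 lists of the comparison), and that of the immediate early list gave -0.312 (p = 0.264, adjusted p = 0.726). Both tests divided the mice without regard to sex. Immediate early means of WT mice were 0.636 to 0.855 in males and -0.63 to 0.023 in females. Against WT that mean also differed by -0.405 in Msh3+/- and -0.207 in Msh3-/- (exact permutation p = 0.161 and 0.446), so a value below WT was not particular to Q140. Microglial markers lay above WT in 17 of 18 cases, with Itgam, an integrin subunit of microglia, at 0.14 ± 0.08 (adjusted p = 0.93; camera adjusted p = 0.00329, and adjusted p = 0.632 with an estimated correlation), and the permutation test gave 0.063 (p = 0.375, adjusted p = 0.726). The immediate early and microglia lists had no member called adjusted over the list alone.

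The count for Q140 against WT was 2 genes, both higher, by edgeR, DESeq2, limma with voom weights and limma on the deposited FPKM values. It was 0 outside 10 Mb of Htt and Msh3, by edgeR, DESeq2 and limma with voom weights. Without the 3 libraries apart on the second principal component (Q140 male 1, Q140 x Msh3-/- male 4 and Msh3+/- male 2), edgeR called 1 gene there, the gene model Gm42756 at -0.73, named after its value was seen. The unadjusted p was under 0.05 for 1096 of all 20010 genes. On counts simulated with the spread of these libraries, with 200 genes changed together, the test recovered 58% of genes at 1.2-fold, 90% at 1.5-fold and 100% at 2-fold for this comparison, with 9 false calls among 201. With few true changes these shares would be lower.

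**Figure D3:**
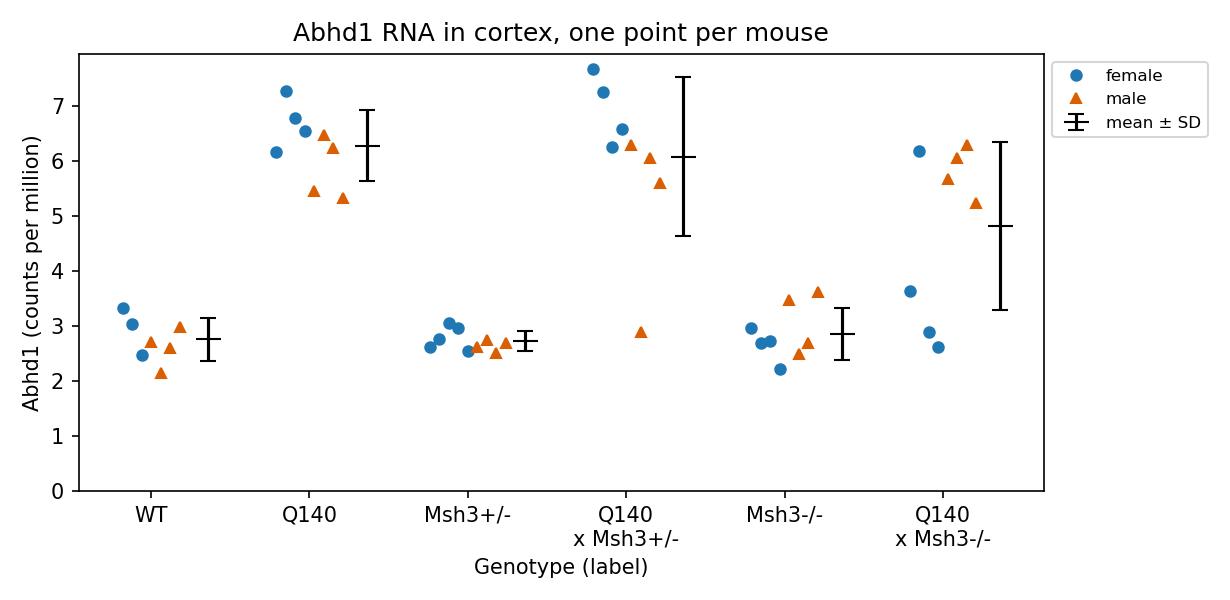
Abhd1 level (CPM, linear axis from 0) in each mouse by genotype group, with the group mean and SD. Of the 24 mice labelled Q140, 20 lie at 5.23 CPM or more and 4 between 2.62 and 3.63, beside at most 3.61 in mice not labelled Q140.

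The Q140 effect was then taken within each altered Msh3 genotype. With a single altered allele, Q140 x Msh3+/- (n = 8) against Msh3+/- (n = 9), Abhd1 rose from 2.73 ± 0.183 to 6.07 ± 1.44 CPM (1.16 ± 0.14, 2.23-fold, adjusted p = 1.91e-06). Gm2420 rose by 2.33 ± 0.41 and Gm44769, an unclassified transcript on chromosome 6, by 0.39 ± 0.07 (both adjusted p = 0.00619), calls lost in 3 of 14 and 2 of 16 alternative settings. These were the 3 genes called, and Abhd1 and Gm2420 were shared with Q140 against WT, where 3e-04 higher genes would be shared if the calls were independent. Both lie near Htt, whose Q140 allele is contrasted in both comparisons, so the calls were linked by the design. Microglial markers lay above Msh3+/- in 16 of 18 cases, with Trem2, a microglial receptor, at 0.24 ± 0.10, and genes of the neurotrophin and activity-dependent list lay below in 12 of 15, with Nrn1, neuritin, at -0.13 ± 0.04 (each adjusted p = 0.78). Camera gave adjusted p-values of 0.01 and 0.0233, and both lists had adjusted p = 0.857 with an estimated correlation and no member called adjusted over the list alone.

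With 2 altered alleles, Q140 x Msh3-/- against Msh3-/- (n = 8 each), edgeR called 0 genes. Abhd1 stood at 4.82 ± 1.53 against 2.86 ± 0.472 CPM (0.75 ± 0.15, adjusted p = 0.0938) and Gm2420 at 2.53 ± 0.54 (adjusted p = 0.233). The 3 mice of this group with Abhd1 at 3.63 CPM or less were females 1, 3 and 4, and without them and the like male 2 of Q140 x Msh3+/-, edgeR called Abhd1 and Gm2420, a set of mice chosen on Abhd1 itself. All 9 choroid plexus markers lay below Msh3-/- (median -2.076), led by Prlr, the prolactin receptor, at -2.01 ± 0.48 and Ttr at -4.92 ± 1.23 (both adjusted p = 0.571, and all 9 called adjusted over the list alone). Camera gave that list an adjusted p of 6.16e-05 (adjusted p = 0.715 with an estimated correlation). Without the 3 libraries with high Ttr, of which 2 are Msh3-/- mice, the value for Ttr turned to 0.26. Immediate early genes lay below Msh3-/- in 22 of 24 cases, with Npas4, an activity-induced transcription factor, at -0.82 ± 0.28 (adjusted p = 0.671; camera adjusted p = 2.47e-05, and adjusted p = 0.715 with an estimated correlation; none called adjusted over the list alone). The unadjusted p was under 0.05 for 1361 genes. DESeq2 called 5 genes, 2 of them near Htt, and limma called 0 with voom weights and 0 on the FPKM values. With the plate column of the well as a factor, edgeR called 12, 2 of them near Htt. Only plate columns 1 and 4 held mice of both groups. Abhd1 gained a call in 3 of 15 alternative settings and Gm2420 in 3 of 13.

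Whether the Q140 effect depended on Msh3 genotype was tested as the difference of the Q140 effects itself. No gene passed for either Msh3 genotype. For Msh3-/- the genes with the smallest p-values included Setmar, a histone methyltransferase gene, at -0.42 ± 0.10, Atxn7, the ataxin gene of another CAG repeat disease, at 0.25 ± 0.06, and Prl, prolactin, at -7.55 ± 1.77 (each adjusted p = 0.922). Prl was also first for Msh3+/-, at -8.43 ± 1.72 (adjusted p = 0.235), and its counts came from few mice: Q140 female 2 had 6.04 CPM, while the mean of all mice was 0.249. Gh, growth hormone, named after its values were seen, was also highest in Q140 female 2, at 2.43 CPM. Next for both genes came Msh3+/- female 1 (Prl 1.87, Gh 0.964) and Q140 female 1 (Prl 1.19, Gh 0.733). High Prl thus went with high Gh in the same libraries, with and without Q140, and the cause was not tested. Med20, a subunit of the Mediator complex, stood at 0.28 ± 0.06 (adjusted p = 0.612). Abhd1, singled out after its values were seen, stood at -0.43 for Msh3-/- (adjusted p = 0.922).

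For Msh3-/- microglial markers had a lower Q140 effect than in WT in 17 of 18 cases, with Cd68, a lysosomal protein of phagocytes, at -0.30 ± 0.13 (adjusted p = 0.922), and the neurotrophin and activity-dependent list a higher one in 12 of 15, with Crem at 0.26 ± 0.12 (adjusted p = 0.922). Camera gave adjusted p-values of 0.00183 and 0.0177, and both lists had adjusted p = 0.912 with an estimated correlation and no member called adjusted over the list alone. For Msh3+/- cholesterol biosynthesis genes had a higher Q140 effect in 22 of 24 cases and immediate early genes in 20 of 24, with Klf4 at 0.69 ± 0.22 (adjusted p = 0.709). Camera gave adjusted p-values of 0.000429 and 0.00124, with adjusted p = 0.991 with an estimated correlation and no member called adjusted over the list alone for both lists. These differences use the WT mice, whose per-mouse means of the immediate early list were 0.636 to 0.855 in males and -0.63 to 0.023 in females. By edgeR 0 genes were called in each of these tests, with an unadjusted p under 0.05 for 1070 genes for Msh3-/- and 1286 for Msh3+/-, and DESeq2, limma with voom weights and limma on the FPKM values also called 0. On simulated differences, with 200 genes changed together, the test for Msh3-/- recovered 40% of genes at 1.2-fold, 84% at 1.5-fold and 100% at 2-fold, with 15 false calls among 193. Fewer true changes would lower these shares. The simulated fold was put into all Q140 x Msh3-/- mice, so the shares would also be lower if the females with low Abhd1 lacked the Q140 allele.

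A score over many genes was used to ask whether a Q140 signature from mice with unaltered Msh3 reappeared in the other genotypes. The signature held the 100 genes with the smallest p in Q140 against WT outside 10 Mb of Htt and Msh3, 49 higher and 51 lower, since no gene there passed the threshold. They include Ttr (-4.41), at 353 CPM in WT male 3, and Prl (5.05), at 6.04 CPM in Q140 female 2, whose counts came from few mice. Genes with large changes weigh more in this mean. Msh3-/- female 4, with Ttr at 1090 CPM, had the lowest score of the 4 groups with an altered Msh3 allele (-0.119). No score without these genes is given. Mice used to choose the genes had mean scores of -0.206 ± 0.059 (WT) and 0.163 ± 0.083 (Q140), which the choice itself sets apart. Scores were -0.019 ± 0.053 in Msh3-/- and -0.005 ± 0.068 in Q140 x Msh3-/-, a difference of 0.014 (n = 8 each, exact permutation p = 0.645 over 12870 ways). They were 0.018 ± 0.043 in Msh3+/- (n = 9) and 0.021 ± 0.042 in Q140 x Msh3+/- (n = 8), a difference of 0.003 (exact permutation p = 0.891 over 24310 ways). Both differences were smaller than the SD between mice of a group, and they differed from each other by 0.011 (exact permutation p = 0.762; Benjamini-Hochberg adjusted p = 0.891 for each of the 3 two-sided tests). In Q140 against WT 5.48% of all genes had an unadjusted p under 0.05, close to the share chance gives. Many of the 100 genes may therefore be chance picks, and a signature of such genes would not reappear in any mice. These scores thus do not show that altered Msh3 removes a Q140 effect. The replicate block, scores centred within sex and replicate number, gave 0.014 for Msh3-/-, 0.006 for Msh3+/- and 0.007 for their difference.

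**Figure D4:**
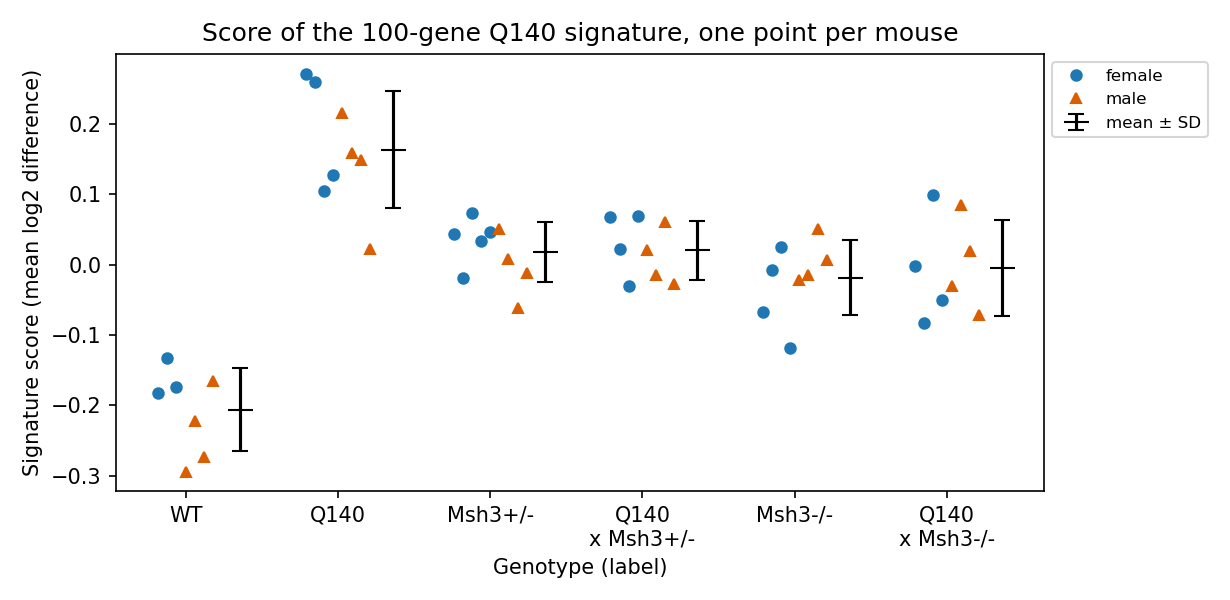
Score of the 100 signature genes (mean signed log2 CPM around the mean of all mice) in each mouse by genotype group, with the group mean and SD. The 4 groups with an altered Msh3 allele, none of them used to choose the genes, have means from -0.019 to 0.021.

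The labels give each animal's sex, so the Q140 effect was also compared between males and females, averaged over the 3 Msh3 genotypes. No gene passed. Tmem176a, a membrane protein gene, stood at 0.25 ± 0.06 and Cluap1, a cilium protein gene, at -0.11 ± 0.03 (both adjusted p = 0.986). As groups, immediate early genes had a lower Q140 effect in males in 22 of 24 cases (median -0.479), with Npas4 at -0.89 ± 0.30, and cholesterol biosynthesis genes in 23 of 24 (median -0.146), with Sqle, squalene epoxidase, at -0.24 ± 0.07 (each adjusted p = 0.986). Deep-layer neuron markers were lower in 18 of 19 cases, with Foxp2 at -0.61 ± 0.22 (adjusted p = 0.986), and interferon response genes higher in 19 of 20, with Rsad2 at 0.62 ± 0.19 (adjusted p = 0.986). Camera gave adjusted p-values of 8.84e-11, 8.84e-11, 1.31e-05 and 0.00123 for these 4 lists, and each had adjusted p = 0.513 with an estimated correlation. Adjusted over the list alone, 1 interferon response gene and no gene of the other lists was called. The males without Q140 include the WT males, whose per-mouse means of the immediate early list were 0.636 to 0.855. EdgeR called 0 genes with an unadjusted p under 0.05 for 897, and DESeq2, limma with voom weights and limma on the FPKM values called 0. On simulated differences, with 200 genes changed together, the test recovered 58% of genes at 1.2-fold, 86% at 1.5-fold and 98% at 2-fold, with 8 false calls among 194. Here too, fewer true changes would lower these shares, as would males labelled Q140 that lacked the allele.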

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

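The tests of the 3 patterns weighed here, and the splits for Q140 against WT, were chosen after the results were seen, while the splits for the other comparisons were fixed before their results. Dixon's gap test of 17 quantities in each of the 6 groups set 1 mouse apart 9 times, and chance does so in about 1 in 20 groups. Ttr stood at 353 CPM in WT male 3, beside 0.963 to 3.88 in the other WT mice, and at 1090 in Msh3-/- female 4, beside 0.641 to 106, the latter in female 3, whose column name has the same stem. The library of WT male 3 also had the highest total, 64.5 M counts beside 42.8 M to 51.3 M. Abhd1 stood at 2.89 CPM and Gm2420 at 0.0781 CPM in Q140 x Msh3+/- male 2, beside at least 5.6 and 0.321 in the other mice of its group. Cmya5 stood at 8.07 CPM in Msh3+/- female 4, beside 11.8 to 14.6, and at 10 CPM in Q140 x Msh3-/- male 4, beside 7.92 to 8.77. F2rl2 stood at 3.54 CPM in WT male 4, beside 2.44 to 2.82, and at 2.47 in Q140 x Msh3+/- female 2, beside 1.51 to 1.88.

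The first pattern is that Msh3 RNA, against a reading of the labels as loss of that RNA, rose with each altered Msh3 allele. Single wrong labels are excluded as its cause, since 0 mice lay in the range of another number of altered alleles. RNA transcribed from the altered allele itself, for instance an inserted promoter or a stable partial transcript, may account for the rise: the mean of mice with 1 altered allele lay 0.49 of the way from 0 to 2 alleles, so each allele added about the same amount. That value would also follow from a change of transcription at an intact gene, and without counts per exon these cannot be told apart, nor was a biological cause tested.

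The next pattern is that genes called with Msh3 genotype lie around Msh3. Calls without regard to position are excluded for Msh3-/- against WT (Fisher's exact p = 2.48e-16 for genes within 10 Mb against others). DNA of another strain kept around Msh3 from the making of the allele is a candidate explanation, because mice with 1 altered allele lay a median of 0.5 of the way over the called neighbours, from 0.43 for AW495222 to 0.61 for F2r, as additive cis variants would give. A local effect of the altered locus would give the same median but would follow the Msh3 allele. Cmya5, AW495222 and F2r did not in Msh3+/- female 4 (8.07, 1.76 and 7.21 CPM, near the level with 2 altered alleles, at 72.5 CPM of Msh3). In WT male 3, at 23.8 CPM of Msh3, Cmya5 and F2r lay near the level with 1 (13.3 and 5.06 CPM). AW495222 lay at 2.64 CPM in that mouse, within the range with 2 (1.49 to 2.85). F2rl2, Fam169a and Rasgrf2 stayed in the range of their group (2.41, 76.2 and 271 CPM in the first mouse, 2.64, 74.9 and 309 in the second). So 1 crossover would not explain the first mouse. As these are the only 2 mice with their prefix of the column name, a local effect and linked variants both stay open. A change of RNA elsewhere with the altered alleles stays open: by edgeR 0 genes outside the region were called in Msh3-/- against WT, with an unadjusted p under 0.05 for 1146 of all genes, while DESeq2 and limma with voom weights each called 6 there.

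The last pattern is that 4 of the 24 mice labelled Q140 had low Abhd1: females 1, 3 and 4 of Q140 x Msh3-/- and male 2 of Q140 x Msh3+/-, at 3.63 CPM or less, where the other 20 had at least 5.23. Gm2420 and Atraid, from the same part of chromosome 5, also lay at the level of mice not labelled Q140 in these 4 (medians 0.0546 and 35.9 CPM, beside 0.0421 and 35.2), and not at that of the other Q140 mice (0.479 and 29.6). An exchange of labels with mice of this series is excluded, since 0 mice not labelled Q140 had Abhd1 in the range of the other Q140 mice. A crossover between Htt and these genes, which would leave the expanded allele in place, may be the cause, but 0 called genes lay on the far side of Htt to show it. Single wrong Q140 labels cannot be told apart from it, because Htt RNA does not mark the allele (0.002 for the Q140 effect averaged over Msh3 genotypes), and no biological explanation was tested.

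How often other splits of the mice gave as many called genes was counted over 100 splits per comparison, the real one included. At 0.05 for each comparison alone, few splits reached the real count for Q140 against WT, with 4 splits at the real count of 2 or more (highest other 8), for Msh3+/- against WT with 3 splits (real 5, highest other 298), for Q140 x Msh3-/- against Q140 with 1 (real 9, highest other 2), for Q140 x Msh3+/- against Q140 with 3 (real 4, highest other 229) and for Q140 x Msh3+/- against Msh3+/- with 1 (real 3, highest other 1). These shares are not corrected over the comparisons. The splits also treat mice as independent, though mice sharing a stem of the column name deviated together, so they do not exclude chance. For Msh3-/- against WT the count alone did not stand apart from other splits, as 24 splits called 7 genes or more (highest other 19). Splits that called 298 or 229 genes point to a structure of the mice other than genotype, and which one was not tested. Where the real count was 0 every one of the 100 splits reached it, and the highest other was 9 for Q140 x Msh3-/- against Msh3-/-, 4 and 3 for the differences of Q140 effects in Msh3-/- and Msh3+/-, and 1 for the sex difference.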

How the results depend on the processing

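Settings without sets of libraries that stood apart, the random block for the stem of the column name, and the counts for averaged effects and for sex, were chosen after the data were seen. Of the values that answer a comparison, 280 under an alternative kept their direction and side of the threshold, while 23 counts moved by more than 1.5 times, 6 values changed sign, 7 counts fell to 0 and 3 rose from 0. Of single genes 3908 kept both, while 84 lost and 28 gained a call and 2 changed sign. Counts below are genes called; the cause was not tested where none is given. With genes near Htt and Msh3 left out, which removes the called neighbours by construction, the count was 0 for Q140 against WT, Msh3-/- against WT, Q140 x Msh3-/- against Q140, Q140 x Msh3+/- against Q140 and both averaged effects, and 1 for Msh3+/- against WT and for Q140 x Msh3+/- against Msh3+/-. With the stricter filter, which drops Gm2420, Q140 against WT had 1. DESeq2 gave 14 for Msh3-/- against WT, 12 for Msh3+/- against WT, 5 for Q140 x Msh3-/- against Msh3-/-, 12 for the averaged Q140 effect and 31 for the averaged Msh3-/- effect. Limma with voom weights gave 14 for Msh3-/- against WT and 13 and 37 for the averaged Q140 and Msh3-/- effects, and limma on log2(FPKM + 0.1) gave 3 for averaged Q140. Limma with voom weights and a random block for mice sharing a stem (correlation 0.108) gave 12 for Msh3-/- against WT, 4 of them outside the region of Msh3, 2 for Q140 x Msh3+/- against Msh3+/-, and 13 and 22 for the averaged Q140 and Msh3-/- effects. With the plate column as a factor the counts were 1 for Msh3+/- against WT, 12 for Q140 x Msh3-/- against Msh3-/-, 1 for Q140 x Msh3+/- against Msh3+/- and 4 for averaged Q140. Genotype groups were spread unevenly over the plate columns, so this factor overlaps in part with genotype. With only the compared groups, Msh3+/- against WT had 2. Replicate numbers of the titles do not pair mice across groups (r from -0.35 to 0.31 for the same number). The averaged Q140 effect had 4 with the replicate block, 4 without the 3 libraries with choroid plexus RNA, and 4 without the 4 libraries labelled Q140 with low Abhd1. Without those 4 libraries, Q140 x Msh3-/- against Msh3-/- had 2, Q140 x Msh3+/- against Msh3+/- had 5 and the averaged Msh3-/- effect had 11. Leaving out each mouse in turn gave 2 to 2 for Q140 against WT, 8 to 12 for Q140 x Msh3-/- against Q140 and 0 to 0 for the difference of Q140 effects between Msh3-/- and WT. Both differences of Q140 effects and the sex difference stayed at 0 in all settings tried. Of the 58 list calls by camera, the estimated correlation left 0 and fry 4. The signature differences changed sign under some settings while staying below the spread between mice: the difference between Msh3 genotypes was -0.038 with higher genes only and -0.005 without the 4 libraries with low Abhd1, that of Msh3-/- was -0.014 with higher genes only, and that of Msh3+/- was -0.023 with genes divided by their SD, -0.003 on log2(FPKM + 0.1) and -0.017 with lower genes only. A signature at an adjusted p under 0.01 could not be computed, as no genes were left. Without the 3 libraries with choroid plexus RNA, 2 of them Msh3-/- mice and 1 WT, Ttr turned to 0.261 in Q140 x Msh3-/- against Msh3-/- and 0.548 in the averaged Q140 effect. Counts near the floor limit Gm2420, at a mean of 0.213 CPM.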

Other observations

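The comparisons in this part were chosen after the data were seen, as were their tests, apart from the splits, which were fixed before their results. More genes differed by sex than in any genotype comparison: with genotype in the model, 546 genes were higher and 566 lower in males (n = 24) than in females (n = 24). The highest other split within genotypes called 29, and 1 of 100 splits reached the real count of 1112. Every stem of the column names held mice of the same sex, and mice sharing a stem deviated together. The fit and the splits treat mice as independent, so what the stems share can add to the count for sex. No count for sex with a block for the stem is given. Besides the Y-linked genes and the X-inactivation transcript Xist, the X-linked translation factor gene Eif2s3x was lower by -0.62 ± 0.03 in males. Of the cholesterol biosynthesis genes, 22 of 24 lay above the female level, 9 were called higher and 16 adjusted over the list alone, led by Lss, lanosterol synthase, at 0.15 ± 0.03 (adjusted p = 0.0042; camera adjusted p = 1.34e-08, and adjusted p = 0.327 with an estimated correlation). All 24 immediate early genes lay above the female level and 4 were called, or 12 adjusted over the list alone, among them Fosb at 0.50 ± 0.13 (adjusted p = 0.0164) and Egr4 at 0.45 ± 0.13 (adjusted p = 0.0261, a call lost in 4 of 13 alternative settings; camera adjusted p = 7.37e-07, and adjusted p = 0.521 with an estimated correlation). The clustered beta protocadherins, adhesion molecules of the neuronal surface, had 7 of 21 members called lower and 11 adjusted over the list alone, led by Pcdhb2 at -0.40 ± 0.06 (adjusted p = 8.86e-06; camera adjusted p = 2.46e-07, and adjusted p = 0.132 with an estimated correlation). All 20 interferon response genes lay below the female level, 2 of them called and 5 adjusted over the list alone, with Ifit1 at -0.25 ± 0.06 (adjusted p = 0.0144; camera adjusted p = 1.04e-05, and adjusted p = 0.319 with an estimated correlation).

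Averaged over the 3 Msh3 genotypes (24 mice with Q140 and 24 without), the Q140 effect held 7 called genes, 3 higher and 4 lower, where 1 of 100 splits reached that count and the highest other had 1. Of these, 4 lay near Htt: Abhd1 at 1.03 ± 0.08, Gm2420 at 2.73 ± 0.28, Atraid at -0.20 ± 0.03 and the mitochondrial ribosomal protein gene Mrpl33 at 0.19 ± 0.04. Elsewhere Car2, a carbonic anhydrase of oligodendrocytes, fell by 0.13 (SE 0.02, adjusted p = 0.0311) and Plpp3, a lipid phosphatase, by 0.09 (SE 0.02, adjusted p = 0.036). Of the 15 alternative settings tried for each, Plpp3 lost its call in 10 and Car2 in 4, and Mrpl33 lost its call in 3 of 14. With the genes near Htt and Msh3 left out before the correction, edgeR called 0 of the rest. All 15 genes of the neurotrophin and activity-dependent list lay below the mice without Q140 (median -0.105), led by Nptx2, a secreted pentraxin of active synapses, at -0.34 ± 0.08 (adjusted p = 0.238; 6 members called adjusted over the list alone; camera adjusted p = 5.57e-11, and adjusted p = 0.134 with an estimated correlation). Astrocyte genes lay below in 14 of 16 cases, with Ndrg2 at -0.09 ± 0.02 (adjusted p = 0.25; 5 members called adjusted over the list alone; camera adjusted p = 1.47e-06, and adjusted p = 0.214 with an estimated correlation). These averages include the WT and Q140 mice of the report, so they are no independent repeat of it.

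Averaged over both Htt genotypes, mice with 2 altered Msh3 alleles differed from mice with 0 in 17 called genes, 9 higher and 8 lower, where 2 of 100 splits reached that count and the highest other had 20. Of these, 12 lay within 10 Mb of Msh3, with Crhbp, which binds corticotropin-releasing hormone and marks some interneurons, higher by 0.27 ± 0.05 (adjusted p = 0.00151) and Ankrd34b lower by -0.22 ± 0.04 (adjusted p = 0.000348). Outside that region, but on the same chromosome, Nnt, the mitochondrial transhydrogenase gene at 119335448 on chromosome 13, rose by 0.52 ± 0.10 (adjusted p = 0.00704). Also outside it, Rgs17, a regulator of G-protein signalling, rose by 0.15 ± 0.03 (adjusted p = 0.039), and Rela, an NF-kappa B subunit, fell by 0.13 (SE 0.03, adjusted p = 0.0186). Of the 15 alternative settings tried for each, Rgs17 lost its call in 8, Rela in 5 and Nnt in 3. The count outside that region moved from 5 to 0 with the genes near Htt and Msh3 left out before the correction, 2 with no low-count filter, 17 with DESeq2 and 25 with limma and voom weights, so which genes change there stays open. The unadjusted p was under 0.05 for 1855 of all genes (9.27%). Nnt differed widely between mice of a group, from 20.8 to 31.6 CPM in WT, 21.2 to 40.1 in Msh3+/- and 25.1 to 44.7 in Q140 x Msh3-/-. These ranges overlap, so the number of altered Msh3 alleles alone did not set its level. Wdfy1 and Ide, named after their values were seen, also varied within groups. In WT they spanned 15.3 to 36.8 and 51.6 to 86 CPM, and in Q140 x Msh3+/- 15.3 to 38.5 and 53.9 to 114. Whether DNA of another strain differs between mice at these genes was not tested.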
